A study of Mus musculus with 6 samples.

How the data were processed

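The data are 1-colour microarray values of 6 samples of whole mouse blastocysts, 3 cultured with a miR-30d mimic and 3 with a scrambled control. Groups and replicate numbers come from the sample titles. Per the labels, RNA was extracted with a column kit for small samples, checked on a capillary chip, labelled with Cy3 by amplification with T7 RNA polymerase and hybridised. The titles call the samples biological replicates. The culture was done in triplicate per the series' design text, and whether the 3 cultures of a group came from separate matings or days is not stated, so p-values measure the spread between these samples.

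The deposited table holds log2 signal for 45220 features on 6 arrays. The array software, background correction and normalization are not given in the sources used here. Array medians were 7.367 to 7.376 and the distributions nearly coincide, as they do after quantile normalization, so the scale was read from the values. The values are not centred per probe, and their direction is that of plain signal. The method is not known, and the arrays differ in their maxima (15.75 to 16) and in their number of distinct values (2108 to 5979). If the arrays were brought to a common scale, a change in total RNA content, or one shared by most genes, cannot be seen in these values. No detection flags or background readings were used here. A dim feature therefore has no known detection limit, and the log2 differences of dim genes can understate the true ones. The median level of the features without a gene name was 7.22, close to the level of Itgb3 in the scramble group.

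Features were named from the platform annotation supplied with the table. Of the 45220 features 33026 had 1 gene symbol, 0 had several and 12194 had none, controls among them, and the unnamed ones were left out. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, which matched 32438 features (98.2%), and the array's name was kept otherwise. The array's own genome build is not given in the sources used here, so no coordinates are printed. Probe names were not used, so repeated features of the same probe could not be averaged and each counts as a probe. The named features represent 22485 genes.

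Probes in the lowest 25% by mean over all 6 arrays were left out, which kept 24769 probes. For each gene the probe with the highest mean was used, giving 17399 genes. Mimic and scramble were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 differences are mimic minus scramble, with the moderated standard error. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, with adjustment over the 22 lists. A list's median was also set against 10000 random lists of the same size matched on mean level. Every p called adjusted for a list is from camera with the preset correlation unless another test is named. The lists are the study's adhesion genes, integrins and cadherins, trophectoderm, inner cell mass and epiblast, primitive endoderm, cleavage stage, oocyte, implantation, p53 and apoptosis, interferon response, reported miR-30 targets, microRNA machinery, cell cycle, stress response, glycolysis and hypoxia, cholesterol synthesis, and markers of endothelial, cumulus, oviduct, sperm, blood and stromal cells. Older symbols were matched through the gene table only where the symbol is not the current name of another gene. This condition was added after results had been seen, when 2 members of the glycolysis list were found matched to other genes, and it changed no camera call of a list. The figures were drawn with matplotlib 3.10.9.

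The genes named were set by a rule fixed before the data were examined. It takes up to 10 genes in each direction by fold change among those past the threshold, filled to 10 with the smallest unadjusted p among genes whose groups do not overlap. It always includes Itgb3, Itga7 and Cdh5, and takes the 3 genes with the smallest unadjusted p in each list. No gene passed, so both sets of 10 were filled by p and their members did not pass.

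Replicate numbers were checked for pairing before any calls were compared. The deviations of same-numbered arrays from their group means correlated at 0.336 for replicate 1, 0.352 for replicate 2 and 0.209 for replicate 3, and each array correlated best with its own number in the other group. By the rule used here (every pair over 0.1) the numbers pair the samples. Differently numbered arrays also exceeded 0.1, with 0.196 for scramble replicate 2 and mimic replicate 3 and 0.129 for scramble replicate 3 and mimic replicate 2. The rule therefore hardly tells replicate 2 from replicate 3, and the replicate 1 arrays share a quality pattern described below. This pairing is read from the data, since the labels do not say that a number marks a shared day. The model without the block stayed the main one, and the blocked value is given where it changes a call or a count of calls by more than 1.5 times.

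The procedure was tested on simulated data with 200 changed genes in each of 5 rounds over 17399 genes, mimic against scramble. Without the block limma recovered 27.6% of 2-fold, 81.5% of 4-fold and 89.4% of 8-fold changes with 1 false call in all rounds, and with the block 2.1%, 50.6% and 74.2% with 4 false calls. Among 200 simulated lists without a shift camera gave p under 0.05 in 2%, and it called all 50 lists of 20 genes that had been shifted by 0.5 log2 units. The simulated genes varied independently, and same-numbered arrays shared no effect. These rates therefore do not cover lists whose members vary together, nor a block on arrays that are paired. The full change was added to genes drawn from all levels, whereas the array can understate changes of dim genes. Recovery can thus be lower for dim genes, and also where fewer than 200 genes change. The alternatives were quantile normalization applied again, centring arrays on the median or the 75th percentile, other filters on dim probes, limma without the trend, with robust estimation or with array weights, an ordinary equal-variance test per gene, other thresholds, the mean of a gene's probes, the replicate block and the omission of each array. Omitting both replicate 1 arrays, and joining the block with an estimated correlation, were added after the data had been examined. The planned comparison of genes with and without miR-30 seed matches was not run, because no transcript sequences were used here.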

Results

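Gene expression was measured in whole mouse blastocysts of the B6C3F1 hybrid strain on day 5, after 72 hours of culture with 400 nM of a synthetic RNA. In 3 samples the RNA was a mimic of miR-30d, a microRNA of the miR-30 family, and in 3 samples it was a scrambled control oligonucleotide carrying the dye Alexa 488. Each condition used 30 embryos, and 50 ng of total RNA per sample was labelled with Cy3 and hybridised to its own array. The study concerns microRNAs that the endometrium releases and that the embryo can meet before it implants. The comparison of mimic with scramble asks which embryonic transcripts differ when miR-30d is supplied from outside. The dye is described here for the control alone, and no untreated embryos were arrayed. Effects of the dye or of either oligonucleotide as such therefore cannot be told apart from those of miR-30d. After dim probes were left out, 17399 genes were tested. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.249.

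The transcripts with the smallest p-values among those higher in the mimic-treated embryos included 4 genes that differed by more than 2-fold, of which Itga7 is described with the adhesion genes below. Ctsll3, which encodes a cathepsin L-like protease, had a mean log2 signal of 12.40 ± 0.38 (SD, n = 3) with scramble and 14.37 ± 0.59 (SD, n = 3) with the mimic, a 3.93-fold difference. Prl3d2, a gene of the placental lactogen family of trophoblast giant cells, had 7.87 ± 0.56 and 9.93 ± 0.40 (SD, n = 3 each), and Anxa1, which encodes a calcium-dependent membrane-binding protein, had a log2 difference of 1.05 (SE 0.20). The lysosomal peptidase gene Ctsc (0.87, SE 0.14), the glutamate transporter gene Slc1a1 (0.90, SE 0.18), the endoplasmic reticulum stress-inducible factor Manf (0.70, SE 0.14), the giant cadherin gene Fat1 (0.64, SE 0.13), the transcriptional regulator Zfp703 (0.66, SE 0.14) and the tubulin gene Tuba1a (0.61, SE 0.13) had smaller log2 differences. The 10 features of Slc1a1 had log2 differences from 0.82 to 0.97. None of these genes passed the adjusted threshold in the limma fit, in which the smallest adjusted p was 0.972. With the replicate number as a block, Ctsll3 alone of the 17399 genes passed, at an adjusted p of 0.0138.

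Among the transcripts with lower signal in mimic-treated embryos were 3 members of the PRAME-like family, whose members are expressed in early embryos and germ cells. Pramel4 had a mean log2 signal of 10.72 ± 0.25 (SD, n = 3) with scramble and 9.52 ± 0.38 (SD, n = 3) with the mimic, and Pramel24 had 10.08 ± 0.47 and 8.67 ± 0.33 (SD, n = 3 each). The log2 difference of Pramel7 was -0.69 (SE 0.13). The 3 features of Pramel24 ranged from -1.41 to -0.34. The cytochrome P450 gene Cyp2s1 (-0.91, SE 0.16), the monoacylglycerol lipase gene Mgll (-0.85, SE 0.18), the hydrolase gene Cmbl (-0.82, SE 0.18), the F-box gene Fbxo9 (-0.76, SE 0.17), Tuft1 (-0.69, SE 0.11) and Fxyd6, which encodes a regulator of the sodium pump (-0.65, SE 0.13), were also on this side. Sertad2 had a log2 difference of -0.92 (SE 0.19) on its brightest feature, but its 3 features went from -0.92 to 0.50. None of these genes passed the adjusted threshold in the limma fit, with or without the replicate block.

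**Figure D1:**
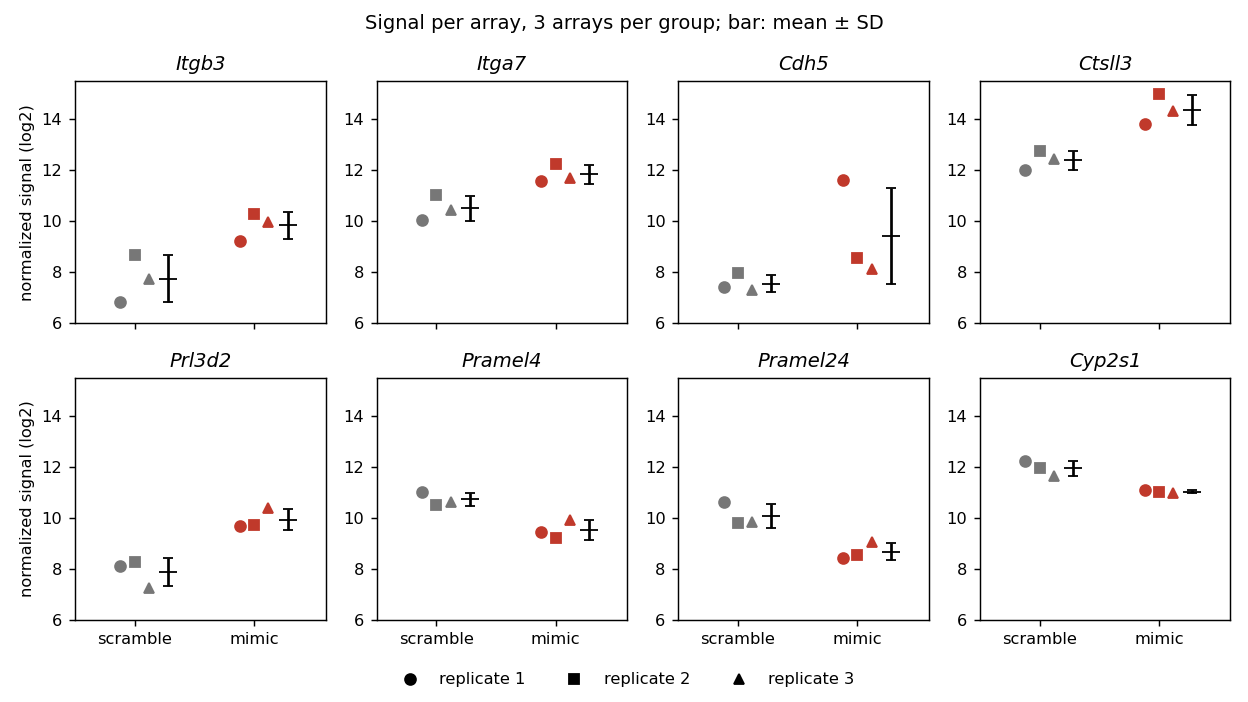
Normalized log2 signal of 8 genes on each of the 6 arrays, with scramble in grey, mimic in red, a marker shape for each replicate number and bars for the mean ± SD of 3 arrays. All 3 mimic values lie above all 3 scramble values for Itgb3, Itga7, Cdh5, Ctsll3 and Prl3d2 and below them for Pramel4, Pramel24 and Cyp2s1, and the Cdh5 value of mimic replicate 1 (11.60) stands far above the other 5.

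Over all genes, limma called 0 of 17399 at an adjusted p of 0.05, and 552 genes (3.17%) had an unadjusted p under 0.05, 289 higher and 263 lower with the mimic. At the level of probes, 0 of 24769 passed and 770 (3.11%) had an unadjusted p under 0.05. With the replicate block 1 gene and 1 probe passed, both of them Ctsll3, and 1260 genes had an unadjusted p under 0.05. Without both replicate 1 arrays, an alternative added after the data had been examined, 0 genes passed and 1000 had an unadjusted p under 0.05. The mimic and scramble values did not overlap in 1687 genes (9.7%), where 10% would be expected of freely exchangeable arrays. In the 9 other groupings of the arrays into 3 and 3 this count went from 893 to 3996, and from 893 to 1086 in the 3 of them that also part all same-numbered pairs.

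The study's paper, as remembered, reports the adhesion genes Itgb3, Itga7 and Cdh5 as higher after the mimic, and all 3 were higher here. Itgb3, the beta 3 integrin subunit that takes part in attachment of the blastocyst, had a mean log2 signal of 7.75 ± 0.92 (SD, n = 3) with scramble and 9.83 ± 0.54 (SD, n = 3) with the mimic, a log2 difference of 2.08 (SE 0.47). Itga7, a laminin-binding integrin subunit, had 10.51 ± 0.49 and 11.84 ± 0.36 (SD, n = 3 each), a log2 difference of 1.33 (SE 0.27). Cdh5, the cadherin of endothelial junctions, had 7.56 ± 0.35 and 9.42 ± 1.90 (SD, n = 3 each), and its log2 difference of 1.87 (SE 0.80) came mostly from mimic replicate 1. That array read 11.60, the other mimic arrays read 8.56 and 8.11, and without it the log2 difference of Cdh5 was 0.78. A second feature of Itgb3 lay near the dim end of the array and had a log2 difference of 0.30. In a two-sided exact permutation test each of the 3 genes reached p = 0.1, the smallest that 3 arrays against 3 allow, and the second Itgb3 feature gave p = 0.3.

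Adjusted over all genes, 0 of the 3 adhesion genes passed in the limma fit. With p adjusted over the list alone 3 of 3 passed, which is not independent evidence, because the study chose these genes on these samples. As a list they stood above other genes in camera with its preset correlation (adjusted p = 1.90e-05), a call that was lost with an estimated correlation (adjusted p = 0.256 with an estimated correlation). The wider family of integrins and cadherins did not pass as a list. Of 29 members tested 17 were higher and 12 lower, the median log2 difference was 0.05, and 2 passed with p adjusted over the list alone, Itga7 and Itgb3 (camera adjusted p = 0.608 for the list). The median went from -0.02 to 0.09 with each array left out in turn.

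Of 22 gene lists fixed before the data were examined, 4 besides the adhesion genes were higher with the mimic in camera with the preset correlation, and each of these calls was lost with an estimated correlation. In the stress response list, which joins heat shock, unfolded protein, integrated stress and oxidative stress genes, 16 of 19 members were higher and 3 lower, with a median log2 difference of 0.26 (adjusted p = 0.00101, and adjusted p = 0.719 with an estimated correlation). The transcription factor gene Atf4 had a log2 difference of 0.82 (SE 0.31), and the endoplasmic reticulum genes Sdf2l1 and Herpud1 had 0.75 (SE 0.29) and 0.47 (SE 0.15). Sdf2l1 fell to 0.50 without scramble replicate 1 and to 0.34 without both replicate 1 arrays. In the list of p53 targets and apoptosis genes, 15 of 21 were higher and 6 lower, with a median of 0.26 (adjusted p = 0.0043, and adjusted p = 0.719 with an estimated correlation). Plk2, Phlda3 and Aen, all induced by p53, had log2 differences of 0.72 (SE 0.26), 0.48 (SE 0.17) and 0.40 (SE 0.15). The stress median was 0.16 without mimic replicate 2 and 0.39 without scramble replicate 2, and the p53 median was 0.14 without scramble replicate 1 and 0.43 without mimic replicate 1. With p adjusted over the list alone 0 members of either list passed, and with the replicate block 4 stress genes and 5 p53 genes passed on that basis.

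In the cholesterol synthesis list 14 of 17 members were higher and 3 lower, with a median log2 difference of 0.24 (adjusted p = 0.0043, and adjusted p = 0.719 with an estimated correlation). The mevalonate pathway genes Fdps, Mvd and Pmvk had log2 differences of 0.42 (SE 0.21), 0.34 (SE 0.17) and 0.25 (SE 0.13). The median was 0.10 and Fdps had 0.19 without scramble replicate 1, and Fdps had 0.27 without both replicate 1 arrays. No member passed with p adjusted over the list alone, with or without the replicate block. The call of this list was also lost without scramble replicate 1 (adjusted p = 0.423), without mimic replicate 2 (adjusted p = 0.058) and without mimic replicate 3 (adjusted p = 0.139).

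Among the lineages of the blastocyst, the primitive endoderm markers were higher on balance, 18 of 22, with a median log2 difference of 0.23 (camera adjusted p = 0.0088, and adjusted p = 0.719 with an estimated correlation). Cubn, the endocytic receptor cubilin, had a log2 difference of 0.52 (SE 0.16) and the collagen chaperone gene Serpinh1 had 0.35 (SE 0.13), while the water channel gene Aqp8 had -0.47 (SE 0.17). This call was lost without scramble replicate 1 (adjusted p = 0.15), mimic replicate 1 (adjusted p = 0.0612), mimic replicate 2 (adjusted p = 0.0956) and both replicate 1 arrays (adjusted p = 0.318), where the median was 0.15 and Cubn had 0.34. The trophectoderm list did not pass, with 8 of 24 higher and 16 lower and a median of -0.05 against a mean of 0.0023 (adjusted p = 0.535). This median was -0.11 without scramble replicate 1 and 0.03 without mimic replicate 1. In it Hand1, a regulator of trophoblast giant cells, had a log2 difference of 1.07 (SE 0.41), Tfap2c 0.43 (SE 0.18) and the endocytic adaptor gene Dab2 -0.47 (SE 0.14). Hand1 had 0.71 without mimic replicate 2. The list of inner cell mass and epiblast genes had 12 of 21 higher and a median of 0.08, while its mean was -0.0095 and camera ranked it on the lower side (adjusted p = 0.698). Its median went from -0.09 to 0.05 with each array left out in turn, and was -0.0074 without both replicate 1 arrays. Nanog, a pluripotency factor, had -0.34 (SE 0.17), Tfcp2l1 -0.26 (SE 0.15) and Utf1 0.35 (SE 0.21). Leaving out scramble replicate 1 reduced them to -0.18, -0.13 and 0.23, and without both replicate 1 arrays Nanog had -0.18 and Utf1 0.08. Utf1 had 0.20 without mimic replicate 1 and 0.55 without mimic replicate 3. With p adjusted over the list alone 0 genes of these 3 lists passed, and with the replicate block 6 primitive endoderm, 7 trophectoderm and 0 inner cell mass genes did.

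**Figure D2:**
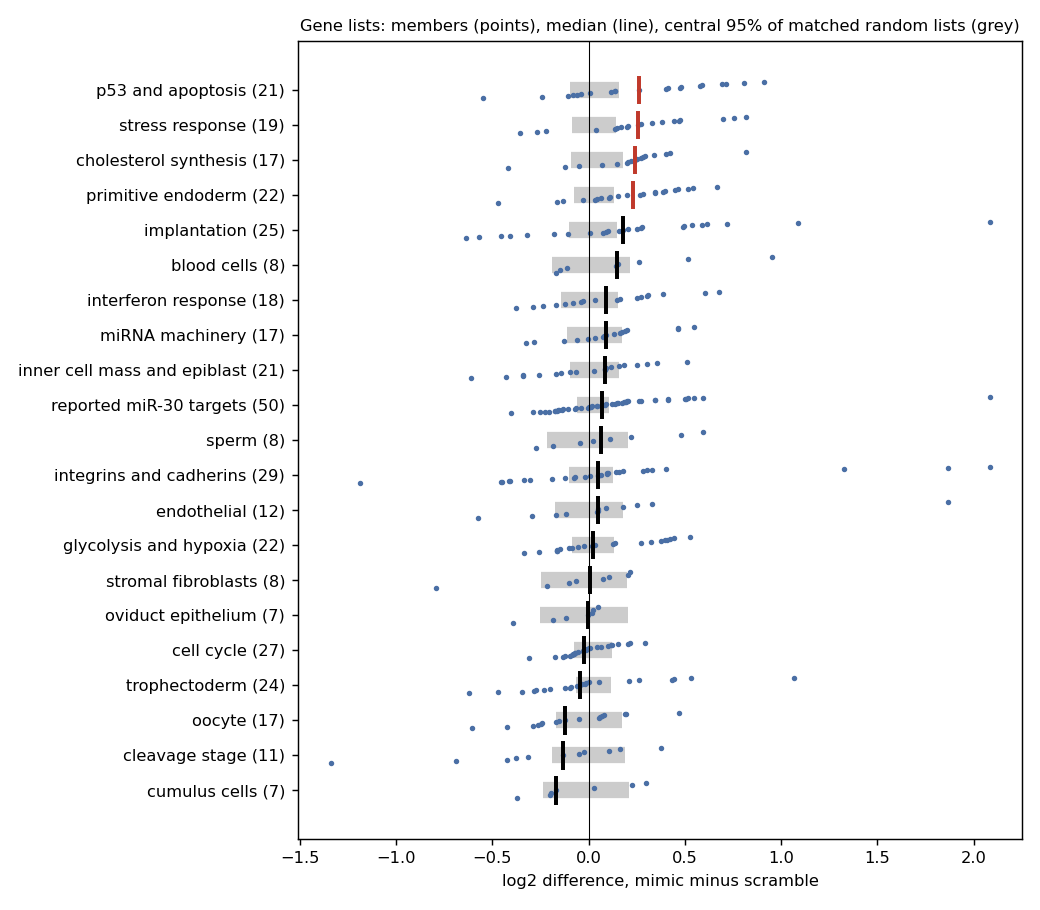
Log2 difference, mimic minus scramble, for the members of 21 gene lists, the 3 adhesion genes of the study being left out. Points are genes, vertical lines medians (red where camera with the preset correlation passed), grey bars the central 95% of medians of 10000 random lists matched on mean level, and numbers in brackets the genes tested. The 4 red medians, from 0.23 to 0.26, lie to the right of their grey bars.

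Genes reported as targets of miR-30 did not pass as a list and were not lower in the median, although microRNAs as a rule reduce the messengers they target. Of 50 tested 33 were higher and 17 lower, with a median log2 difference of 0.07 (camera adjusted p = 0.18), which went from 0.04 to 0.15 with each array left out in turn. Itgb3 belongs to this list, and the cytokine-signalling inhibitor Socs3 had 0.50 (SE 0.23) and the polyadenylation factor gene Cpsf2 0.60 (SE 0.36). Both rested largely on a low reading of scramble replicate 1, without which Socs3 had 0.25 and Cpsf2 0.22, and without both replicate 1 arrays they had 0.33 and 0.34. None of the 50 passed with p adjusted over the list alone, and 1 did with the replicate block. Of 17 genes of the microRNA machinery 12 were higher, with a median of 0.09 (adjusted p = 0.426), and Dicer1, Tnrc6a and Mov10 had log2 differences of 0.47 (SE 0.28), 0.55 (SE 0.40) and -0.32 (SE 0.26). The median of the machinery genes was 0.20 without scramble replicate 2. Leaving out scramble replicate 1 gave 0.23 for Dicer1, 0.14 for Tnrc6a and -0.10 for Mov10, and leaving out both replicate 1 arrays gave 0.26, 0.27 and -0.33. Tnrc6a had 0.88 and Mov10 -0.50 without scramble replicate 2, and Mov10 had -0.56 without mimic replicate 1 and -0.16 without mimic replicate 2. Interferon response genes, which respond to foreign RNA, had 10 of 18 higher and a median of 0.09 (adjusted p = 0.449), which was 0.03 without scramble replicate 1 and -0.07 without both replicate 1 arrays. Both groups received a synthetic RNA, so a response common to both would not show here. The list also lay near the dim end, at a median level of 7.34. Bst2 had 0.39 (SE 0.16), the RNA sensor gene Ddx58 0.68 (SE 0.34) and Usp18 0.30 (SE 0.17). Ddx58 fell to 0.35 without scramble replicate 1 and to 0.44 without both replicate 1 arrays. In the machinery and interferon lists 0 genes passed with p adjusted over the list alone.

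Of 25 implantation genes 18 were higher, with a median log2 difference of 0.18 (camera adjusted p = 0.0764, and adjusted p = 0.0491 without scramble replicate 3 and 0.0411 without mimic replicate 3). Without both replicate 1 arrays the median was 0.08 (adjusted p = 0.318), and it was 0.10 without mimic replicate 1 and 0.30 without mimic replicate 3. Itgb3 passed with p adjusted over the list alone, which is not independent evidence since the study chose it on these samples, and 2 genes did with the replicate block. Timp2 had 1.09 (SE 0.80), with an isolated bright value on mimic replicate 1 (10.75, against at most 8.20 on the other arrays). Lifr, a receptor for leukaemia inhibitory factor, had 0.49 (SE 0.16) and the urokinase gene Plau 0.59 (SE 0.20). Cleavage-stage genes had 8 of 11 lower and a median of -0.13 (adjusted p = 0.0764, and adjusted p = 0.0189 without scramble replicate 2 and 0.0352 without scramble replicate 3), and Pramel7 passed with p adjusted over the list alone. Pramel6 had a log2 difference of -0.38 (SE 0.22) and Arg2 of -0.31 (SE 0.21), and without scramble replicate 1 they had -0.19 and -0.17. Without both replicate 1 arrays they had -0.20 and -0.19, and the median of this list was 0.07 (adjusted p = 0.888). Pramel6 had -0.60 without scramble replicate 3. The median of the cleavage-stage list went from -0.28 to 0.07 with each array left out in turn. Oocyte genes had 10 of 17 lower and a median of -0.12 (adjusted p = 0.407), with Nlrp5 at 0.47 (SE 0.24), Nlrp4f at -0.60 (SE 0.32) and Zar1 at -0.42 (SE 0.23). Nlrp5 had 0.28 without mimic replicate 1, Nlrp4f -0.36 without scramble replicate 1 and Zar1 -0.25 without scramble replicate 3. Nlrp5 fell to 0.14 and Nlrp4f to -0.23 without both replicate 1 arrays. The oocyte median went from -0.15 to -0.03 with each array left out in turn. Cell cycle genes were close to even, with 11 of 27 higher and a median of -0.02 (adjusted p = 0.535, and adjusted p = 0.0416 on the lower side without scramble replicate 1). Cenpa had -0.31 (SE 0.19), Mcm7 -0.17 (SE 0.14) and Cenpf 0.30 (SE 0.29), the last of which was -0.15 without both replicate 1 arrays. Cenpa went to -0.15 without mimic replicate 1 and -0.20 without scramble replicate 3. Mcm7 ranged from -0.28 without scramble replicate 1 to -0.10 without scramble replicate 2, and Cenpf from 0.06 without scramble replicate 1 to 0.51 without scramble replicate 3. The median of the cell cycle list went from -0.09 to 0.06 in the same way. Glycolysis and hypoxia genes had 12 of 22 higher and a median of 0.02 (adjusted p = 0.426, and adjusted p = 0.0468 on the higher side without mimic replicate 1). The glucose transporter gene Slc2a1 had 0.41 (SE 0.13), Gapdh 0.42 (SE 0.26) and Pgk1 0.40 (SE 0.25). Without scramble replicate 1 Gapdh had 0.24, Pgk1 0.18 and the median was -0.09, while without scramble replicate 3 the median was 0.13. Pgk1 had 0.64 without scramble replicate 2, and without mimic replicate 2 Gapdh had 0.28 and Pgk1 0.26. In the oocyte, cell cycle and glycolysis lists 0 genes passed with p adjusted over the list alone, and 5 glycolysis genes did with the replicate block.

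Markers of cells that flushed embryos could carry along did not pass as lists in the main setting of camera, and most lay near the dim end of the array. Endothelial markers had 8 of 12 higher and a median of 0.05 (adjusted p = 0.698), with Esam at -0.58 (SE 0.21) and Egfl7 at 0.25 (SE 0.14) beside Cdh5. The endothelial median was -0.09 and Egfl7 had 0.16 without both replicate 1 arrays. Blood cell markers had 5 of 8 higher and a median of 0.15 (adjusted p = 0.369, and adjusted p = 0.719 with an estimated correlation). They passed with the lower 50% of probes left out (adjusted p = 0.03) and without mimic replicate 2 (adjusted p = 0.0215), but without both replicate 1 arrays the median was -0.02 (adjusted p = 0.869). It was -0.12 without mimic replicate 1 and 0.04 without scramble replicate 2. The calcium-binding protein genes S100a8 and S100a9 had 0.96 (SE 0.34) and 0.52 (SE 0.18), and Cd14 had 0.15 (SE 0.17). S100a8 had 0.58 without scramble replicate 1 and 0.495 without both replicate 1 arrays, and Cd14 had 0.08 without mimic replicate 1. Cumulus cell markers had 3 of 7 higher and a median of -0.17 (adjusted p = 0.694), with Nr5a2 at -0.37 (SE 0.21), Ptgs2 at 0.30 (SE 0.20) and Has2 at 0.23 (SE 0.21). The level of Nr5a2 was 10.81 with scramble and 10.44 with the mimic, against 7.14 to 7.45 for Ptgs2 and Has2. Its signal therefore need not come from cumulus cells. Nr5a2 had -0.17 without mimic replicate 2, Ptgs2 0.17 without scramble replicate 2 and Has2 0.08 without mimic replicate 1, and the median was 0.12 without scramble replicate 1. Oviduct markers had 3 of 7 higher and a median of -0.0034 (adjusted p = 0.426), with Foxj1 at -0.39 (SE 0.21), Rsph1 at -0.18 (SE 0.29) and Ovgp1 at -0.12 (SE 0.20). Foxj1 had -0.26 without mimic replicate 1, Rsph1 0.15 without scramble replicate 3 and Ovgp1 0.04 without mimic replicate 3, and without both replicate 1 arrays Foxj1 had -0.14 and Rsph1 -0.42. Sperm markers had 5 of 8 higher and a median of 0.07 (adjusted p = 0.698), with Gapdhs at 0.48 (SE 0.23) and Odf1 at -0.28 (SE 0.19). Gapdhs had 0.28 without mimic replicate 1 and Odf1 -0.17 without scramble replicate 3. Odf2 had 0.59 (SE 0.56), -0.15 without scramble replicate 1, 1.08 without scramble replicate 2 and -0.14 without both replicate 1 arrays. Stromal fibroblast markers had 4 of 8 higher and a median of 0.0052, while camera ranked them on the lower side (adjusted p = 0.716). Postn had -0.79 (SE 0.40), Col3a1 0.20 (SE 0.21) and Des 0.22 (SE 0.26), the last of which was 0.0074 without mimic replicate 1 and -0.06 without both replicate 1 arrays. Postn had -0.43 and Col3a1 0.03 without scramble replicate 1, Postn had -1.23 without scramble replicate 2, and Col3a1 had 0.09 without mimic replicate 3. The medians of the endothelial (-0.05 to 0.19), cumulus (-0.24 to 0.12), oviduct (-0.08 to 0.0034), sperm (-0.02 to 0.13) and stromal lists (-0.09 to 0.03) all changed sign with some array left out. For cumulus, oviduct, sperm and stromal markers the medians were 0.0043, 0.02, 0.04 and 0.03 without both replicate 1 arrays. With p adjusted over the list alone 0 genes of these 6 lists passed.

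The replicate 1 arrays of both groups stood apart from the other 4. Scramble replicate 1 held 2108 distinct values and mimic replicate 1 held 2683, against 4410 to 5979 on the others. Their mean correlations across features with the other 5 arrays were 0.911 and 0.936, against 0.956 to 0.962. They held 100 and 68 named features over 2 log2 units brighter than on all other arrays, against 2 to 9. Cdh5 on mimic replicate 1 was among the 68. Features of intermediate level, from 8 to 9.5, read lower on these arrays by a mean log2 shift of -0.43 and -0.24. These features were picked by their mean on the other 4 arrays, and the shift was measured against that same mean. Only the replicate 1 arrays were held out of the choice, so part of this contrast is set by construction. Of the 78 genes tested that are named here by rule, 24 had a log2 difference that moved by over 1.5 times without scramble replicate 1, 13 without mimic replicate 1 and 26 without both. Genes at levels 8 to 9 had a median log2 difference between mimic and scramble of 0.10, and of 0.04 without both replicate 1 arrays. Correlations between arrays of the same group, 0.913 to 0.990, spanned the same range as those between groups, 0.907 to 0.990, where both are taken across features, which are not independent replicates.

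**Figure D3:**
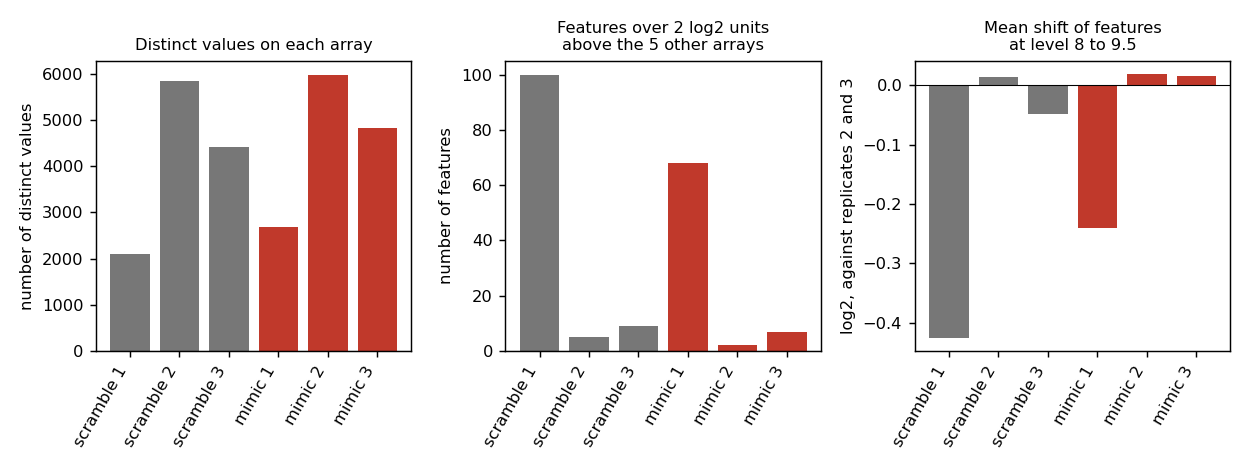
Number of distinct values, number of named features over 2 log2 units above the 5 other arrays, and mean log2 shift of features at level 8 to 9.5, for each of the 6 arrays (scramble in grey, mimic in red, bars starting at 0). The replicate 1 arrays have the fewest distinct values (2108 and 2683), the most isolated bright features (100 and 68) and the lowest shifts (-0.43 and -0.24). Features for the shift were picked by, and shifts taken against, the mean of the replicate 2 and 3 arrays. The replicate 1 shifts are thus partly set by construction.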

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

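Results here are counts, list p-values and log2 differences of mimic against scramble, and leaving out both replicate 1 arrays or joining the block with an estimated correlation was chosen after seeing the data. The count of genes past the threshold stayed at 0 under every other normalization, filter, limma variant and per-gene test run and with each array left out, with 362 to 1208 genes at an unadjusted p under 0.05. The exceptions were the replicate block (1 gene and 1 probe) and the threshold of 2-fold with unadjusted p under 0.05 (36 genes and 50 probes), which uses no adjustment. With array weights the smallest adjusted p was 0.0713. Apart from Ctsll3, the replicate block changed no call over all genes, and it changed no camera call of a list at the preset correlation. Precision is limited by 6 arrays and by unknown background, and 8925 of the genes tested had a mean level under 8. The comparison of miR-30 seed matches was not run, nor were its alternatives.

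Camera with an estimated correlation, fry, and the block with an estimated correlation each called 0 lists, where camera with the preset correlation called 5. For the adhesion genes the adjusted p was 0.256, 0.233 and 0.555 in that order, for stress response 0.719, 0.566 and 0.497, for p53 and apoptosis 0.719, 0.566 and 0.497, for cholesterol synthesis 0.719, 0.661 and 0.555, and for primitive endoderm 0.719, 0.603 and 0.555. The members of the cholesterol list had an estimated correlation of 0.638, far above the preset 0.01. With each array left out, camera's adjusted p went from 4.96e-05 to 0.423 for cholesterol synthesis and from 0.000507 to 0.15 for primitive endoderm, and leaving out both replicate 1 arrays gave 0.318 for the latter. The adhesion, stress and p53 lists kept their calls with each array left out. Cleavage-stage genes, not called in the main setting, passed on the lower side without a filter on dim probes (0.0167) and with the lower 50% left out (0.0161), and blood cell markers passed on the higher side in the latter setting (0.03). With 1 array left out further lists passed that the main setting did not call. These were cleavage-stage genes without scramble replicate 2 (0.0189) or 3 (0.0352) and cell cycle genes without scramble replicate 1 (0.0416), both on the lower side. On the higher side they were implantation genes without scramble replicate 3 (0.0491) or mimic replicate 3 (0.0411), glycolysis genes without mimic replicate 1 (0.0468) and blood cell markers without mimic replicate 2 (0.0215).

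Directions of values not called in the main setting were less stable, and the cause was not tested. Without a filter on dim probes camera's direction turned for cumulus (adjusted p = 0.837) and sperm markers (0.65). Without both replicate 1 arrays it turned for cleavage-stage (0.888), interferon response (0.965) and endothelial genes (0.58), and log2 differences turned for Cenpf (-0.15), Odf2 (-0.14) and Des (-0.064). Array weights turned Cenpf (-0.10) and Des (-0.054), and the mean of a gene's probes turned Des (-0.19). With each array left out, log2 differences went from -0.37 to 0.15 for Rsph1, -0.25 to 0.037 for Ovgp1 and -0.15 to 1.08 for Odf2. Lists whose direction turned with some array left out had adjusted p from 0.0189 to 0.962 (cleavage stage), 0.0416 to 0.755 (cell cycle), 0.0468 to 0.92 (glycolysis and hypoxia), 0.264 to 0.754 (interferon response), 0.478 to 0.923 (inner cell mass and epiblast), 0.478 to 0.962 (endothelial), 0.455 to 0.827 (cumulus), 0.48 to 0.976 (sperm) and 0.653 to 0.962 (stromal).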

Other observations

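The tests of Cdh5, of lost signal on the replicate 1 arrays, of correlated list members, of replicate 1 values and trophectoderm share for Ctsll3 and Prl3d2, and of the splits without the adhesion list were chosen after the results were seen. The genes named in this part beyond those of the report were also picked after their values were seen, and none of them passed the adjusted threshold in limma (adjusted p = 0.972 for each unless another is given).

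At 2-fold or more with an unadjusted p under 0.05 there were 36 genes, 22 higher and 14 lower with the mimic. Among the higher ones was Hpgd, which encodes the enzyme that inactivates prostaglandins, with a mean log2 signal of 7.77 ± 0.49 (SD, n = 3) under scramble and 9.39 ± 0.62 (SD, n = 3) under the mimic. Nfkbia, the inhibitor of NF-kappa-B, had a log2 difference of 1.14 (SE 0.26), the homeobox genes Irx1 and Otx2 had 1.18 (SE 0.48) and 1.11 (SE 0.34), and the membrane glycoprotein gene Gp2 had 1.24 (SE 0.31). On the lower side were the phosphodiesterase gene Pde4c (-1.05, SE 0.25) and Cox6a2, a cytochrome c oxidase subunit (-1.10, SE 0.30). Without both replicate 1 arrays 13 of the 36 still differed by 2-fold or more, 7 higher and 6 lower, Hpgd (1.71), Gp2 (1.07) and Irx1 (1.21) among them, while Nfkbia had 0.91, Otx2 0.73, Pde4c -0.88 and Cox6a2 -0.82. For 4 of the 36 the value of a single replicate 1 array stood over 2 log2 units above all others, Cdh5, Hspb8 and Tcl1b4 on mimic replicate 1 and Sgcd on scramble replicate 1.

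Of 21 PRAME family members whose values had not been seen when the list was written, Pramel5 had the smallest p, with a log2 difference of -0.81 (SE 0.22). Over all 21, Pramel5 included, 16 were lower and the median was -0.125, with p = 0.0313 in camera with an estimated correlation and 0.125 after adjustment over the 4 families tested this way, and 16 of the 21 lay below level 8. At camera's preset correlation the 21 passed on the lower side (adjusted p = 0.012 over the 4 families, and 0.00796 without both replicate 1 arrays, where the median was -0.087). A shared fall of the family therefore stays open. Fos and Dusp1, genes induced within minutes of a stimulus, had 0.67 (SE 0.26) and 0.57 (SE 0.24), and 29 further immediate early genes had a median of 0.0885 (adjusted p = 0.711 in camera with an estimated correlation, over the 4 families). Their median was 0.157 over the 18 at level 8 or more and 0.127 without both replicate 1 arrays, where they passed at the preset correlation (adjusted p = 0.00796 over the 4 families), so a shared rise stays open. Anxa4 (0.62, SE 0.14) and S100a6 (0.70, SE 0.18) lay on the same side as Anxa1, but 21 further annexin and S100 genes had a median of -0.0061 (adjusted p = 0.904 in the same test).

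Cdh5 was higher with the mimic mainly through mimic replicate 1, where it exceeded the mean of the other arrays by 3.73 log2 units. Endothelial cells in that sample are argued against, because the 11 other endothelial markers exceeded the other arrays there by a median of 0.228 (95% bootstrap bounds -0.264 to 0.491) and at most 0.863. An isolated bright value on that array remains a candidate explanation for the greater part of the difference, since the log2 difference without it was 0.778 and the array held 68 such features against 2 to 9 on the arrays of replicates 2 and 3. An effect of the mimic on Cdh5 stays open as well, because the other mimic arrays also lay above all scramble arrays. A response of 1 culture alone was not tested.

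The stress, p53, cholesterol and primitive endoderm lists were higher with the mimic at camera's preset correlation. A shift shared by all genes of similar level is argued against as the whole source, since 4 of 4 medians lay above the central 95% of level-matched random lists. These lists had already been picked by camera on the same values, and the random lists leave out members varying together. The comparison therefore does not tell whether the lists differ beyond such shared variation. Signal lost on the replicate 1 arrays is argued against for stress and p53, which passed without both of those arrays (adjusted p = 0.000199 and 3.35e-05). Without scramble replicate 1 alone the p53 call was kept (adjusted p = 0.0395), though its median was 0.14. The cholesterol list also passed without both arrays (adjusted p = 0.00401). Without scramble replicate 1 alone its median was 0.10 and its call ended (adjusted p = 0.423), so for this list lost signal stays open. For primitive endoderm lost signal cannot be told apart from an effect, because the call ended without both arrays (adjusted p = 0.318) while the median stayed at 0.626 of its full value on 4 arrays. Members of a list varying together between arrays of the same group could account for the cholesterol and primitive endoderm calls, since the adjusted p with an estimated correlation was 0.719 for each and correlations of 0.158 and 0.146 remained with the replicate block. For stress and p53 the estimated correlations were 0.275 and 0.182 without the block, where the adjusted p was also 0.719 for each. With the block they were -0.048 and -0.031, and the adjusted p was 0.497 for each. Shared variation could thus account for these 2 calls without the block, but with it this cannot be told. A response of the embryos stays open as well.

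Ctsll3 and Prl3d2, which belong to gene families of the placenta, were about 4-fold higher with the mimic. The values of the replicate 1 arrays are argued against as the source, because without both arrays the mean log2 difference of the pair was 2.19, against 2.02 with them. For a larger share of trophectoderm cells, the trophectoderm list had a median of -0.0469, far below the change of the pair. Its members already read high (median level 12.1) in these whole blastocysts, so a larger share could hardly move them near 4-fold. The list therefore cannot decide whether the share differed. A change in the kinds of trophectoderm cells was not tested. Of the 24 members 16 were lower and 8 higher, Hand1 (1.07, SE 0.41) among the higher and Cdx2 (-0.62, SE 0.28) among the lower. For a placental programme further advanced in mimic-treated embryos, 51 placental genes not seen before were listed and 28 were tested, 18 higher and 10 lower. Plac1 had the smallest p, with a log2 difference of 0.59 (SE 0.17), and Cts7 the next, with -0.84 (SE 0.28). Without both replicate 1 arrays they had 0.56 and -0.58. The 28 genes had a median of 0.101, below the 0.2 set beforehand. Their 95% bootstrap bounds were -0.0033 to 0.198, and their median was -0.0176 without both replicate 1 arrays. The 12 of them at level 8 or more, a condition added after seeing the result, had 0.0416 (bounds -0.156 to 0.177). A rise of these genes near that of the pair is argued against as far as the array can read them. A smaller rise stays open, since the bounds resample genes and leave out the spread between cultures. The upper bound also lies just under 0.2, and 16 of the 28 lay below level 8. An effect of the mimic on these 2 genes alone, or a difference in stage between cultures, was not tested.

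The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 552 genes at an unadjusted p under 0.05 and the highest other split 2407, and 5 of the 10 splits, the real one included, gave as many as the real one. The other 4 of these 5 put both replicate 1 arrays in the same group (679 to 2407 genes), which points to a structure of the samples, while the 3 other splits that, like the real one, part all 3 same-numbered pairs gave 124 to 145. For genes and probes past the adjusted threshold all 10 of 10 splits gave 0. For gene lists at the preset correlation the real split called 5 and the highest other 4, and 1 of the 10 splits, the real one, gave as many, but the adhesion list was chosen by the study on the real split. Without it the real split called 4 and the highest other 4, and 2 of the 10 splits gave as many. The other split with 4 puts both replicate 1 arrays in the same group, and the 3 other splits that part all same-numbered pairs called 0 to 2.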
